A study of Drosophila melanogaster with 54 samples.

How the data were processed

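RNA was measured in 54 single embryos of Drosophila melanogaster at 8 stages of embryonic development. The labels give the stage of each embryo, and a letter in its title names it within the stage. Per the labels' protocols, embryos were picked by hand, staged by their morphology, and crushed in lysis buffer, and a mix of synthetic spike-in RNAs was added. Ribosomal RNA was then depleted and paired-end libraries were sequenced on an Illumina instrument. Per the labels, 8 of the libraries were made without strand information. The labels give neither the sex of an embryo nor its parents or its collection, so p-values measure the spread between these embryos.

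The authors deposited 1 table of counts per embryo, holding whole-number counts of reads per gene, not normalized. The layout is that of the aligner's own count output, with 3 columns: reads without regard to strand, reads for the strand of read 1, and reads for the opposite strand. Per the submitters' processing notes the aligner was STAR 2.5.3a and the genome build dm6. The gene annotation behind the counts is not given in the sources used here. Each table has 17481 gene entries and 4 summary entries. These hold reads that were unmapped, assigned to no gene, in several genes or in several places. The summary entries stayed out of library sizes and tests. Reads assigned to no gene, which may include reads of introns, made up 0.298 to 10.6% of those assigned to a gene, to several genes or to none. Reads in several genes made up 4.17 to 5.64%. Counts in genes were 13.1 to 26.5% of all reads, with a median of 16.4%. Most of the other reads were in the unmapped entry. In stage 4 embryo B, for example, it held 43030883 reads against 12863155 in genes, and the entry for several places held 0. The spike-in RNAs were not used here, because 0 gene entries stood for them, so levels are relative to the RNA of the embryo's own genes.

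Symbols and positions came from annotation release 115 of the build BDGP6.54, matched on the gene identifiers of the tables. Of the 17481 identifiers, 17343 had a symbol and a position and 138 did not. Coordinates are those of BDGP6.54.

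The counts without regard to strand were used throughout, because they treat both kinds of library alike. The stranded columns showed 46 directional libraries, with 96.7 to 97.5% of gene reads on the opposite strand, and 8 non-directional libraries, with 50.3 to 50.5%. The non-directional libraries were embryos A, B, F and G of stage 13 and of stage 15. Without strand, the reads of a gene and of an overlapping gene cannot be told apart. Of 295 named genes, 4 had under 80% of their reads on their own strand in the directional libraries. These were Alp4 with 16.8%, para with 16.8%, Hml with 20.8% and dsx with 26.2%, and their values are uncertain. Reads shared with overlapping genes were left uncounted, which lowers dpn, knk and eve. Members of gene families that share sequence, such as the paralogous ribosomal protein genes, may have split reads.

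Gene counts per embryo ranged from 1632448 to 12863155, with a median of 4713817, and 7842 to 12934 genes had a count. At the median depth, 1 CPM, a gene count relative to the library size after TMM scaling, rests on about 5 reads, so low genes carry large counting error. Intervals and floors cover counting error only. A fold against a stage whose embryos were all at 0 was computed against 3 reads over the whole stage and is written as at least that fold. Where a stage held 1 to 3 reads of a gene, levels are given in place of a fold. Among the 168 pairs of embryos within a stage, the smallest chi-square per degree of freedom was 3.99, so no pair was counted as a single library. Correlations between same-letter embryos of neighbouring stages ran from -0.274 to 0.245, so the title letters marked no strong pairs across stages. For letter B they exceeded the highest correlation with another letter at stages 4 and 5 (0.127 against 0.054) and 5 and 6 (0.202 against 0.015). The same held at stages 8 and 10 (0.143 against 0.055) and 10 and 12 (0.245 against 0.128). It did not hold at stages 6 and 8, 12 and 13 or 13 and 15. The same letters had non-directional libraries at stages 13 and 15, and embryo B had the highest gene counts at stages 4, 5, 6 and 8. A batch shared by a letter therefore cannot be excluded.

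Genes were tested with edgeR 4.0.16 in R 4.3.3. All 54 embryos entered a single quasi-likelihood fit with a mean per stage, TMM scaling and the default filter for low counts, which kept 9783 genes. Of these, 1607 lay on the X, 7985 on the arms 2L, 2R, 3L and 3R, and 86 on chromosome 4. The common biological coefficient of variation was 0.191. Neighbouring stages were compared, and stage 15 with stage 4. Adjusted p-values are Benjamini-Hochberg values over the genes tested, two-sided, with a threshold of 0.05. Log2 changes are given with their standard error (SE), and levels as mean CPM with the SD over embryos. On counts simulated from the fitted levels of stages 4 and 5 over 9676 genes, 74% of genes changed 1.5-fold, 92% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 17.1% of calls were false. In data simulated from stages 6 and 8 over 9677 genes the shares were 64, 96 and 100%, with 7.3% false calls. For stages 13 and 15, over 9667 genes, they were 68, 91 and 100%, with 7.9% false calls. In each simulation 200 genes were changed, as many raised as lowered, and the others were set equal between the stages. In the data 8088 of 9783 genes were called between stages 4 and 5, so these rates need not hold there.

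Lists of genes were fixed before the data were examined, as were the comparisons, the tests and the rule for named genes. The 24 lists were dosage compensation complex, sex determination, maternal regulators, cellularization, dorsoventral patterning, gap and pair-rule, segment polarity, Hox, cell cycle, neuroblast, neuron, glia, muscle, heart, trachea, cuticle and epidermis, hemocyte, gut, salivary gland, ribosomal proteins, mitochondrially encoded, heat shock, eggshell and yolk, and Y-linked. The trachea member esg matched no identifier and was not analysed. The Y-linked list had 0 members among the genes tested. List tests used camera of limma 3.58.1 with a preset correlation of 0.01 between genes and, as an alternative, an estimated correlation, adjusted over 184 tests. Counts of members are given after adjustment over all genes and adjusted over the list alone.

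The named genes of a comparison were the 6 with the largest rise and the 6 with the largest fall among called genes that reached a stage mean of 10 CPM and whose embryos did not overlap between the stages. Genes known only by a CG or CR number were counted and not named. Up to 4 called members of each list with the largest change were added, and all members of the dosage compensation complex and sex determination lists. Among genes that varied between embryos of a stage, the 15 with the largest excess were eligible.

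For each embryo, the X to autosome ratio was the median log2 CPM of X genes minus that of genes on the autosome arms, and stages were compared by an exact two-sided permutation test, adjusted over 8 comparisons. The deviation of the X was the median, over X genes, of the log2 level of an embryo minus its stage mean, less the same median over autosomal genes, with a prior count of 2. The SD of this deviation between embryos of a stage was compared with that of 10000 random sets of autosomal genes matched on expression. In data simulated from stage 8 over 9783 genes, a shift of the X by 0.05 in 2 of 5 embryos gave an SD of 0.0327 where 0.0274 was put in. Zygotic genes were those called at least 2-fold higher at stage 10 than at stage 4, and maternal genes those called at least 2-fold lower.

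Alternatives were DESeq2 1.42.0, size factors of DESeq2 in edgeR, no filter on low counts, the stranded counts of directional libraries, library type as a covariate, the title letter as a replicate block, means in place of medians, another prior count, genes of at least 10 CPM, other numbers of variable genes, and leaving out each embryo in turn. For single genes, values without 1 embryo are given where its omission changed a call or moved a called fold by over 1.5 times, a check made after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the other steps.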

Results

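Development was sampled at stages 4, 5, 6, 8, 10, 12, 13 and 15, from the syncytial blastoderm to embryos in which organs differentiate. Each library was made from a single embryo, with 5 embryos at stage 4, 9 at stage 5, 5 at stage 6, 5 at stage 8, 9 at stage 10, 5 at stage 12, 8 at stage 13 and 8 at stage 15. Reads counted in genes came to 4410384 to 12863155 per embryo at stage 4, 3326516 to 5983843 at stage 5, 3607948 to 7955337 at stage 6 and 2975020 to 7571424 at stage 8. At stages 10, 12, 13 and 15 they came to 2537965 to 5700497, 1632448 to 6304319, 4763446 to 7620647 and 4575463 to 9421310. Genes on the mitochondrial genome took 1.96 to 6.67% of gene counts per embryo, and the 10 most abundant genes took 4.74 to 9.05%. Genes with a mean of at least 10 CPM numbered 5745 at stage 4 and 6702 at stage 15. The title of the series concerns the dosage compensation of the X chromosome, which raises transcription of the single X in males. The comparisons of neighbouring stages ask which genes changed as embryos developed, and those of the X ask how its RNA stood against that of the autosomes. Over the 8 stages, 9755 of 9783 genes differed at an adjusted p under 0.05.

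**Figure D1:**
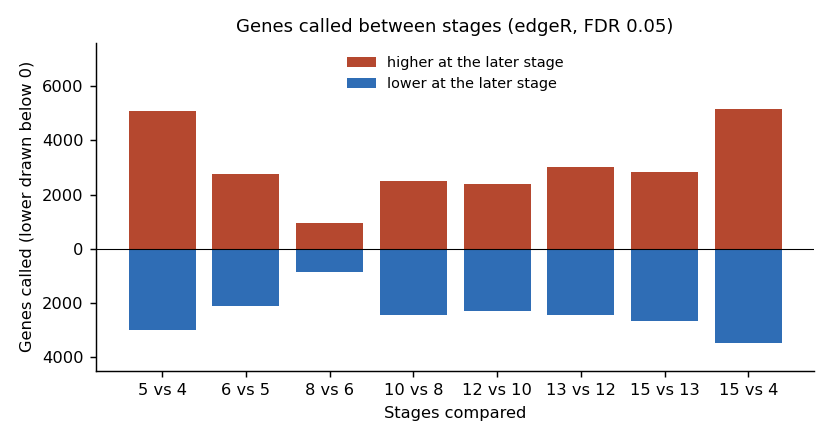
Number of genes with a higher or lower level in the later stage at an adjusted p under 0.05, of 9783 genes tested, for each pair of stages. Bars above 0 count higher genes and bars below 0 count lower genes; the smallest total among neighbouring stages was 1805, between stages 6 and 8.

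Between stage 4 (n = 5) and stage 5 (n = 9), patterning genes with hardly any RNA at stage 4 became abundant, while most maternal regulators declined. Ptr, which encodes a relative of the Patched receptor, rose from 0.318 ± 0.212 to 2378 ± 251 CPM, a log2 change of 12.7 ± 0.40 (adjusted p = 2.27e-33). The POU-domain gene nub had 0 reads at stage 4 and 147 ± 18.3 CPM at stage 5, at least 2180-fold higher. The hindgut gene byn likewise went from 0 reads to 127 ± 37.9 CPM, at least 1890-fold higher. The pair-rule gene opa had 3 reads at stage 4, 0.0398 CPM, and 524 ± 98 CPM at stage 5. Among losses, dhd, a thioredoxin of the female germ line, fell by 7.23 ± 0.54 from 2635 ± 621 to 17.4 ± 3.98 CPM (adjusted p = 1.22e-17).

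Genes that pattern the embryo rose together. All 16 dorsoventral patterning genes rose, with a median log2 change of 8.88, including sog at 12.03 ± 0.28 and brk at 10.38 ± 0.26, which act on the Dpp gradient. The mesoderm gene twi had 3 reads at stage 4, 0.0867 CPM, and 305 ± 26.8 CPM at stage 5. Of 18 gap and pair-rule genes 16 rose and 1 fell, with a median of 9.37, and both lists stayed called with an estimated correlation (adjusted p = 0.0292 and 0.00255). All 8 segment polarity genes rose, with a median of 6.53, or 5.68 with members absent from a stage set to their bound (adjusted p = 0.126 with an estimated correlation). Of these the Hedgehog receptor gene ptc reached 906 ± 124 CPM after 0.433 ± 0.168, and nkd, an antagonist of Wingless signalling, rose by 11.25 ± 0.21. All 8 Hox genes rose, among them Antp by 6.77 ± 0.35, though the list as a whole was not called (adjusted p = 0.0675). Of 15 neuroblast genes 12 rose and 1 fell (adjusted p = 0.0773 with an estimated correlation), with mira, an adaptor for asymmetric division, at 11.19 ± 0.28. Of 9 trachea genes 8 rose (adjusted p = 0.347 with an estimated correlation), with uif at 10.98 ± 0.28. Cellularization genes rose in 7 of 8 cases (adjusted p = 0.243 with an estimated correlation). The furrow gene slam (FBgn0043854) rose from 220 ± 16.9 to 6376 ± 1180 CPM and halo, which directs lipid droplet transport, by 10.59 ± 0.42. Without stage 4 embryo G the rise of Antp was 7.53, and without stage 4 embryo H those of uif and halo were 11.70 and 11.65.

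Of 21 maternal regulators 16 fell and 4 rose, with a median of -2.96 (adjusted p = 0.321 with an estimated correlation). The germ plasm gene osk fell from 1337 ± 152 to 24.1 ± 6.94 CPM, exu by 5.73 ± 0.36, and dl, which encodes the Dorsal protein, by 5.92 ± 0.28. Of 20 cell cycle genes 8 rose and 11 fell. Falls included the cyclin-dependent kinase inhibitor dap with -4.54 ± 0.27, the mitotic phosphatase stg with -3.28 ± 0.14 and CycB with -1.69 ± 0.11. Of 8 heat shock genes 4 fell and 2 rose, with Hsp26 at -6.30 ± 0.47 and Hsp83 at -3.01 ± 0.19. The hemocyte list rose in 7 of 10 members and fell in 1, the scavenger receptor gene crq, which fell by 4.42 ± 0.14. The median of all genes moved by 0.72, by 0.85 with DESeq2 size factors and by 0.87 with the DESeq2 test. Against that shift, the 80 ribosomal protein genes all rose with a median of 1.05 (adjusted p = 0.638 with an estimated correlation) and the 15 mitochondrially encoded genes all rose with a median of 1.46. Eggshell and yolk genes had 3 tested members, of which 1 rose. That list's median was above 0 while its test pointed down, with an adjusted p of 0.94.

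The dosage compensation list changed in every member, in a comparison where 8088 of 9783 genes were called. The list as a whole was not called (adjusted p = 0.483, or 0.889 with an estimated correlation). The noncoding RNA roX1 (FBgn0019661, X 3857230 to 3862697) rose by 10.87 ± 0.80 from 1.19 ± 1.02 to 2017 ± 668 CPM (adjusted p = 6.99e-18). The male-specific protein gene msl-2 (FBgn0005616, 2L 3462218 to 3466112) rose by 5.71 ± 0.70 to 273 ± 147 CPM (adjusted p = 2.3e-10). The helicase gene mle rose by 1.49 ± 0.09, the acetyltransferase gene mof by 0.67 ± 0.28 and Clamp by 0.29 ± 0.10. The rises of mof and Clamp lay below the median change of all genes, 0.72. The noncoding RNA roX2 (FBgn0019660, X 11579065 to 11580432) had 1 read at stage 4, 0.0267 CPM, and 1.94 ± 1.07 CPM at stage 5. Changes of -0.32 ± 0.11 for msl-1 and -0.43 ± 0.20 for msl-3 passed the test, but not with DESeq2 size factors, at -0.19 and -0.31. The call of mof was lost without stage 4 embryo C, D or H or stage 5 embryo H (0.60 to 0.65), and that of msl-3 without stage 4 embryo B or H or stage 5 embryo C, D, E or F (-0.43 to -0.39). That of roX2 was lost without embryo B of stage 4 or embryo B of stage 5 (adjusted p = 0.0628 and 0.0569). Of 17 sex determination genes 14 rose and 1 fell (adjusted p = 0.29 with an estimated correlation). The switch gene Sxl (FBgn0264270, X 7074550 to 7098053) rose by 2.5 ± 0.58 to 1174 ± 792 CPM. Single embryos of stage 5 had 104 to 1963 CPM of Sxl against 160 to 242 CPM at stage 4, so the mean rise did not hold in every embryo. The X-linked counting genes sisA, run and upd1 rose by 5.39 ± 0.53, 7.10 ± 0.44 and 6.61 ± 0.35, or by 6.19, 8.78 and 7.47 without stage 4 embryo H, and sisA by 6.06 without stage 4 embryo G. The splicing regulator tra2 fell by 1.57 ± 0.12. In total 5096 genes were higher and 2992 lower, a share of 63.0% higher, or 53.9% relative to the median. With the DESeq2 test the share was 69.5%. With p adjusted within the list, these counts were the same except for eggshell and yolk, with 0.

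**Figure D2:**
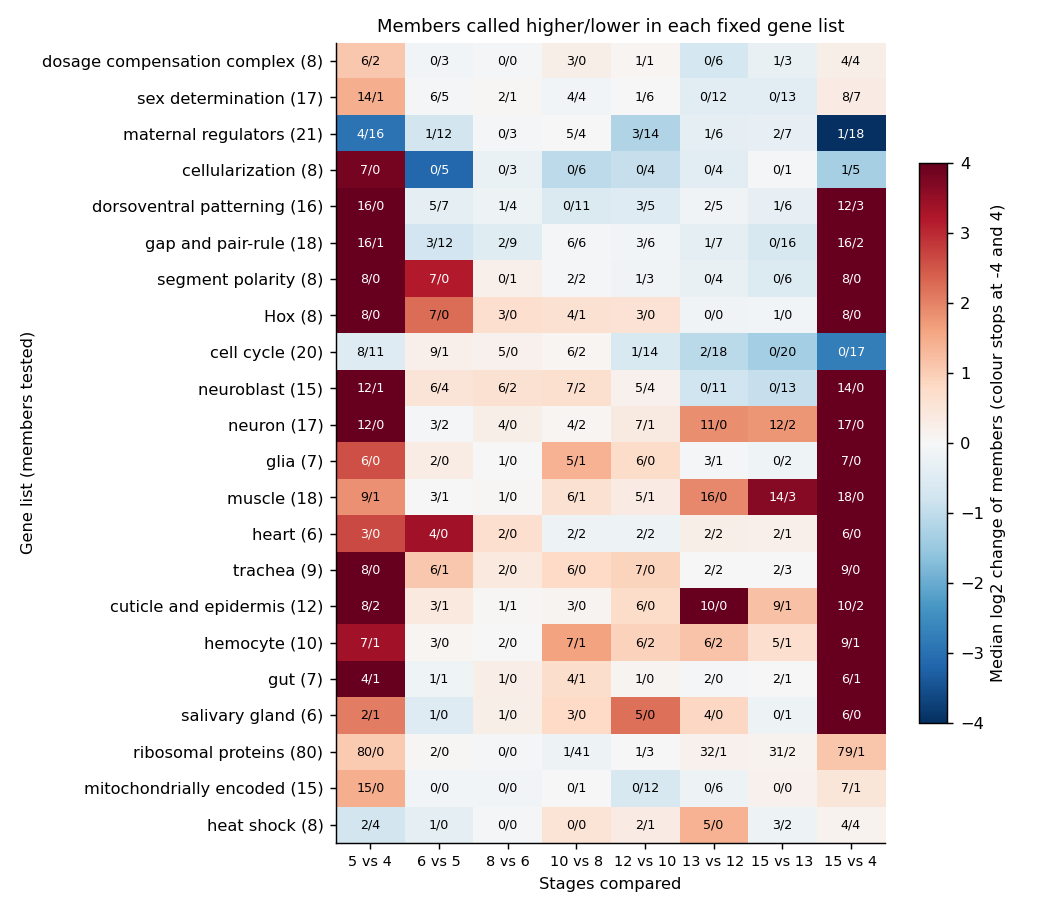
Median log2 change of each fixed gene list (vertical axis, members tested in brackets) between the stages compared (horizontal axis), with the numbers of members higher and lower written in each cell. Colours stop at 4 in either direction, and the median of the dorsoventral patterning list between stages 4 and 5 was 8.88.

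Between stage 5 (n = 9) and stage 6 (n = 5), when gastrulation begins, segment polarity genes rose and 5 of 8 cellularization genes fell. The segment polarity gene en rose from 0.567 ± 0.467 to 90 ± 15.7 CPM, a log2 change of 7.26 ± 0.22 (adjusted p = 5.99e-32). The T-box gene mid rose by 7.17 ± 0.24 and the receptor kinase gene Alk by 6.26 ± 0.37. Conversely, bnk, needed for the timing of actin rearrangement in cellularization, fell by 7.37 ± 0.61, and slam fell from 6376 ± 1180 to 79.8 ± 44.8 CPM. Of 8 segment polarity genes 7 rose, with a median of 3.18, and the call held with an estimated correlation (adjusted p = 0.00049). These included gsb at 5.67 ± 0.21 and hh at 4.24 ± 0.15. Of 6 heart genes 4 rose (adjusted p = 0.0342 with an estimated correlation), including tin, required for the dorsal vessel, at 5.35 ± 0.28. Of 8 Hox genes 7 rose (adjusted p = 0.0543 with an estimated correlation), with Abd-B at 3.69 ± 0.62, Scr at 3.61 ± 0.28 and Antp at 2.91 ± 0.16.

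Of 8 cellularization genes 5 fell (adjusted p = 0.139 with an estimated correlation), and halo and Z600 fell by 4.09 ± 0.27 and 3.77 ± 0.25. Of 21 maternal regulators 12 fell and 1 rose (adjusted p = 0.347 with an estimated correlation). The receptor gene Tl fell from 1709 ± 88.5 to 240.3 ± 43.6 CPM, and twe and tor fell by 2.93 ± 0.26 and 2.55 ± 0.24. Of 18 gap and pair-rule genes 12 fell and 3 rose. In that list tll changed by -2.17 ± 0.41, kni by -1.64 ± 0.18 and slp1 by 1.94 ± 0.16. Of 16 dorsoventral patterning genes 5 rose and 7 fell, with the midline gene sim up by 3.76 ± 0.23. Of 20 cell cycle genes 9 rose and 1 fell (adjusted p = 0.788 with an estimated correlation), led by stg at 2.5 ± 0.14, with the replication licensing gene Mcm2 at 1.47 ± 0.13. Trachea genes rose in 6 of 9 cases and fell in 1 (adjusted p = 0.355 with an estimated correlation), with the FGF gene bnl at 3.13 ± 0.22. The muscle regulator Mef2 rose by 2.62 ± 0.15, the glial switch gene gcm by 2.90 ± 0.29 and the salivary gland gene CrebA by 4.18 ± 0.22.

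Of the dosage compensation list 3 of 8 members fell, Clamp by 0.83 ± 0.10, msl-1 by 0.66 ± 0.12 and mof by 0.66 ± 0.29. The call of mof was marginal (adjusted p = 0.0499) and was lost without stage 5 embryo D, E, G, H or J (-0.67 to -0.59) or stage 6 embryo C or G (-0.46 and -0.47). A rise of msl-3 was called only without stage 5 embryo H or J or stage 6 embryo C or G (0.52 to 0.57). Levels of roX1 at 1678 ± 418 CPM and msl-2 at 290 ± 195 CPM were not called against stage 5 (adjusted p = 0.656 and 0.914). Of the sex determination list 6 rose and 5 fell, including da at 0.72 ± 0.06, sc at 1.84 ± 0.46 and upd1 at -0.94 ± 0.23, and Sxl was not called at 734 ± 576 CPM. In total 2742 genes were higher and 2107 lower. Adjusted over the list alone, 2 dosage compensation, 6 cellularization and 8 dorsoventral patterning genes fell, and the other counts given were the same. Median, mean and test differed in sign for the dorsoventral patterning, sex determination, muscle, cuticle and epidermis, gut, salivary gland, ribosomal protein and eggshell and yolk lists.

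Between stage 6 (n = 5) and stage 8 (n = 5), as the germ band extends, fewer genes were called than between any other neighbouring stages, 959 higher and 846 lower. The Notch target gene E(spl)mgamma-HLH rose from 0.686 ± 0.44 to 45.0 ± 19 CPM, a log2 change of 6.02 ± 0.42 (adjusted p = 1.57e-15), and E(spl)mdelta-HLH by 4.25 ± 0.45. The translation inhibitor gene Thor rose by 3.30 ± 0.76 and the transporter gene Smvt by 3.09 ± 0.49. The insulator factor gene Elba3 fell by 3.12 ± 0.39, Mabi by 2.56 ± 0.38 and the adenylyl cyclase gene Ac78C by 2.20 ± 0.22. Of 17 neuron genes 4 rose (adjusted p = 0.438 with an estimated correlation), with the zinc finger genes scrt and nerfin-1 at 2.92 ± 0.27 and 2.85 ± 0.49. Of 15 neuroblast genes 6 rose and 2 fell. The proneural gene ac rose by 1.57 ± 0.37 and ase, a gene of neural precursors, by 2.77 ± 0.73.

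Of 18 gap and pair-rule genes 9 fell and 2 rose, with a median of -0.50 (adjusted p = 0.201 with an estimated correlation). In this list prd fell by 1.85 ± 0.22, ftz by 1.6 ± 0.32 and opa by 0.73 ± 0.14. Of 8 Hox genes 3 rose (adjusted p = 0.201 with an estimated correlation), with lab at 1.64 ± 0.31. Of 20 cell cycle genes 5 rose (adjusted p = 0.736 with an estimated correlation), with stg at 1.23 ± 0.15. Of 9 trachea genes 2 rose (adjusted p = 0.408 with an estimated correlation), with the FGF receptor gene btl at 2.31 ± 0.23. Mef2 rose by 1.40 ± 0.15 and the endoderm gene GATAe by 2.41 ± 0.29. Cellularization genes fell in 3 of 8 cases, slam by 1.97 ± 0.26, and dorsoventral patterning genes fell in 4 of 16 and rose in 1, zen falling by 1.97 ± 0.35 and dpp rising by 0.84 ± 0.14. In the dosage compensation list 0 of 8 genes were called by edgeR, though a fall of mof was called without stage 6 embryo C or G or stage 8 embryo D or G (-1.16 to -0.98). In the sex determination list her rose by 0.31 ± 0.09, upd1 rose by 0.81 ± 0.25 and gro fell by 0.41 ± 0.07. The call of her was lost without stage 6 embryo H (0.275), and that of upd1 without stage 6 embryo D or H (0.72 and 0.70). With p adjusted within the list, 7 Hox genes rose and 1 fell, 4 gap and pair-rule genes rose and 10 fell, 3 neuroblast and 5 dorsoventral patterning genes fell, and 6 cell cycle and 3 trachea genes rose. Other counts given were the same. Median, mean and test differed in sign for the cuticle and epidermis, hemocyte and heat shock lists.

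Between stage 8 (n = 5) and stage 10 (n = 9), most genes of the trachea and glia lists rose, though neither list stayed called with an estimated correlation. The neuroblast gene wor rose from 0.893 ± 1.1 to 166 ± 56.7 CPM, a log2 change of 7.69 ± 0.39 (adjusted p = 1.84e-21), and ase by 4.79 ± 0.37. The genes axed, Him and Prat2 had 2 reads each at stage 8 and 32.2 ± 34, 26.7 ± 13.4 and 26.8 ± 26 CPM at stage 10. SNCF fell by 6.03 ± 0.28, term by 4.89 ± 0.34 and Elba1 by 4.80 ± 0.49. Of 9 trachea genes 6 rose (adjusted p = 0.153 with an estimated correlation), including the tracheal regulators trh at 5.13 ± 0.27 and vvl at 4.73 ± 0.32, and the apical matrix gene dpy at 3.16 ± 0.28. Of 7 glia genes 5 rose and 1 fell (adjusted p = 0.264 with an estimated correlation), with gcm2 at 4.55 ± 0.51 and moody at 2.11 ± 0.29. Of 15 neuroblast genes 7 rose and 2 fell (adjusted p = 0.321 with an estimated correlation). Without stage 8 embryo C the rise of wor was 8.60, and without stage 8 embryo B that of gcm2 was 5.20.

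The visceral mesoderm genes bap and bin rose by 5.57 ± 0.45 and 5.96 ± 0.67 (bin 6.67 without stage 8 embryo C), and svp, a gene of cardiac and other cells, by 3.96 ± 0.33. In the gut list 4 of 7 genes rose and byn fell, by 2.23 ± 0.48. Of 10 hemocyte genes 7 rose and 1 fell, with the matrix peroxidase gene Pxn at 2.79 ± 0.33, and 6 of 18 muscle genes rose and 1 fell, with the myoblast fusion gene rols at 2.64 ± 0.32. Of 16 dorsoventral patterning genes 11 fell and 0 rose (adjusted p = 0.264 with an estimated correlation), with zen2 at -3.46 ± 0.51 and twi at -1.97 ± 0.20. Cellularization genes fell in 6 of 8 cases (adjusted p = 0.29 with an estimated correlation). Gap and pair-rule genes rose in 6 cases and fell in 6 of 18, prd falling by 3.78 ± 0.23 and opa by 2.79 ± 0.13. Of 8 Hox genes 4 rose and 1 fell, with pb at 3.07 ± 0.42 and Ubx at 1.25 ± 0.21. Of 80 ribosomal protein genes 41 fell and 1 rose, with a median of -0.20 (adjusted p = 0.867 with an estimated correlation), RpL4 falling by 0.35 ± 0.08.

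In the dosage compensation list roX2 rose by 2.31 ± 0.95 from 2.99 ± 1.63 to 15.8 ± 18.2 CPM (adjusted p = 0.038), with 2.39 to 61.1 CPM in single embryos of stage 10, Clamp by 0.34 ± 0.10 and msl-1 by 0.29 ± 0.12, and the other 5 genes were not called. The call of roX2 was lost without stage 8 embryo B, C, G or H (2.07 to 2.38) or stage 10 embryo E (1.71), and that of msl-1 without stage 8 embryo B, C, G or H or stage 10 embryo B or E (0.25 to 0.28). Sex determination genes rose in 4 and fell in 4 of 17 cases, tra rising by 0.98 ± 0.19 and tra2 by 0.78 ± 0.13. In total 2504 genes were higher and 2432 lower. Adjusted over the list alone, 8 neuroblast genes rose and 12 dorsoventral patterning and 47 ribosomal protein genes fell, and the other counts given were the same. Median, mean and test differed in sign for the sex determination, segment polarity and heart lists.

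Between stage 10 (n = 9) and stage 12 (n = 5), as the germ band retracts, most genes of the glia, salivary gland and trachea lists rose and most cell cycle genes fell, though none of these lists stayed called with an estimated correlation. The muscle actin gene Act57B rose from 2.99 ± 2.53 to 284 ± 164 CPM, a log2 change of 6.71 ± 0.31 (adjusted p = 2.43e-23). The small heat shock gene Hsp67Bc rose by 6.77 ± 0.54 and the glutathione transferase gene GstE3 by 5.97 ± 0.66. Oat had 1 read at stage 10 and 19.8 ± 20.1 CPM at stage 12, and Hey, a Notch target, had 2 reads and 10.9 ± 6.11 CPM. Falls were led by moon at -4.68 ± 0.42, the Wnt gene wntD at -4.14 ± 0.39 (-4.81 without stage 12 embryo B), gprs at -3.95 ± 0.47 and the aminopeptidase gene ApepP at -3.93 ± 0.23.

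Of 7 glia genes 6 rose (adjusted p = 0.0773 with an estimated correlation), with the glial regulator repo at 4.64 ± 0.35 (5.32 without stage 10 embryo I) and the midline glia gene wrapper at 4.12 ± 0.34. Of 9 trachea genes 7 rose (adjusted p = 0.25 with an estimated correlation), with vvl at 1.92 ± 0.20. Of 6 salivary gland genes 5 rose, with a median of 2.19 (adjusted p = 0.201 with an estimated correlation), among them the prolyl hydroxylase gene PH4alphaSG2 at 4.82 ± 0.59. Of 20 cell cycle genes 14 fell and 1 rose (adjusted p = 0.611 with an estimated correlation). The gene that rose was dap, from 136 ± 84.6 to 963 ± 124 CPM, while Mcm5, Mcm2 and PCNA fell by 1.25 ± 0.13, 1.03 ± 0.14 and 0.91 ± 0.12. Maternal regulators fell in 14 of 21 cases and rose in 3, without a call with an estimated correlation, with the germ cell gene pgc at -3.75 ± 0.80. Cellularization genes fell in 4 of 8 cases (adjusted p = 0.251 with an estimated correlation), halo by 3.08 ± 0.34, and the mitochondrially encoded genes fell in 12 of 15 (adjusted p = 0.736 with an estimated correlation). Of 17 neuron genes 7 rose and 1 fell, with the RNA-binding protein genes fne at 2.49 ± 0.28 and elav at 1.30 ± 0.15. In the neuroblast list cas rose by 2.69 ± 0.28 and pdm2, which precedes it in neuroblast lineages, fell by 1.21 ± 0.17. Hemocyte genes rose in 6 of 10 cases and fell in 2, with the prophenoloxidase gene PPO1 at 5.06 ± 0.95 and the collagen gene Col4a1 at 3.21 ± 0.36. Muscle genes rose in 5 of 18 cases and fell in 1, with rols at 3.42 ± 0.20, and 3 of 8 Hox genes rose, with abd-A at 1.16 ± 0.22.

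In the dosage compensation list roX2 rose by 2.16 ± 0.67 to 64.4 ± 55.1 CPM (adjusted p = 0.00654). Single embryos had 2.39 to 61.1 CPM of roX2 at stage 10 and 5.17 to 125 CPM at stage 12, where embryos C and G lay within the range of stage 10, so this fold also reflects which embryos were sampled. Without stage 10 embryo E it was 2.76. In the same list mle fell by 0.20 ± 0.08, a call lost when adjusted over the list alone, and without stage 10 embryo G or H or stage 12 embryo C or G (-0.18 to -0.17). Sex determination genes fell in 6 of 17 cases and rose in 1, with upd1 at -1.16 ± 0.24 and vir at -0.64 ± 0.09. In total 2394 genes were higher and 2291 lower. With p adjusted within the list, 7 glia and 7 hemocyte genes rose, 15 maternal regulators and 13 mitochondrially encoded genes fell, and the remaining counts given were the same. Median, mean and test differed in sign for the dosage compensation and heart lists.

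Between stage 12 (n = 5) and stage 13 (n = 8), most genes of the cuticle and epidermis, muscle and neuron lists rose and most genes of the cell cycle and neuroblast lists fell. All 5 of these list calls were lost with an estimated correlation. The chitin deacetylase genes serp and verm rose by 9.93 ± 0.48, from 0.262 ± 0.218 to 226 ± 122 CPM (adjusted p = 2.48e-22), and by 7.43 ± 0.28. Kr-h1, a juvenile hormone response gene, had 0 reads at stage 12 and 18.7 ± 15.8 CPM at stage 13, at least 150.0-fold higher. The methyltransferase gene jhamt of juvenile hormone synthesis had 2 reads and then 57.0 ± 33.1 CPM. The proneural gene ato fell by 4.62 ± 0.52, Brd by 4.40 ± 0.28 and the peroxiredoxin gene Prx6b by 4.24 ± 0.44. Of 12 cuticle and epidermis genes 10 rose, with a median of 4.14 (adjusted p = 0.0773 with an estimated correlation), including obst-A at 4.94 ± 0.31. Without stage 12 embryo G the rises of verm and obst-A were 8.17 and 5.78.

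Of 18 muscle genes 16 rose, with a median of 1.93 (adjusted p = 0.407 with an estimated correlation), including the troponin genes wupA at 4.99 ± 0.84 and up at 4.67 ± 0.93, or 4.14 and 3.79 without stage 13 embryo A. Of 17 neuron genes 11 rose (adjusted p = 0.251 with an estimated correlation). The glutamate transporter gene VGlut had 0 reads at stage 12 and was at least 21-fold higher at stage 13, and fne and Appl rose by 4.28 ± 0.25 and 3.68 ± 0.26. Of 20 cell cycle genes 18 fell and 2 rose, with a median of -1.09 (adjusted p = 0.153 with an estimated correlation). The mitotic genes polo, aurA and BubR1 fell by 1.77 ± 0.13, 1.77 ± 0.18 and 1.77 ± 0.14. Of 15 neuroblast genes 11 fell (adjusted p = 0.243 with an estimated correlation), with the proneural genes ac at -3.47 ± 0.36, l(1)sc at -3.05 ± 0.34 and sc at -2.33 ± 0.42. Of 10 hemocyte genes 6 rose and 2 fell, the collagen genes vkg and Col4a1 by 3.32 ± 0.26 and 3.27 ± 0.28. Heat shock genes rose in 5 of 8 cases, with stv at 5.79 ± 0.55, and 32 of 80 ribosomal protein genes rose and 1 fell.

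In the dosage compensation list 6 of 8 genes fell. The largest change was that of roX1, -1.50 ± 0.43 from 2602 ± 685 to 919 ± 725 CPM (adjusted p = 0.00241), which was not called with library type as a covariate, at -1.10. Single embryos had 1954 to 3662 CPM of roX1 at stage 12 and 367 to 2188 CPM at stage 13, and embryos at high and low levels were not equally frequent at these stages, so means of the list's genes also reflect which embryos were sampled. Falls of 0.84 ± 0.20 for msl-3, 0.79 ± 0.28 for mof and 0.59 ± 0.12 for msl-1 were larger than those of Clamp and mle, and msl-2 at -1.05 ± 0.51 was not called (adjusted p = 0.0751). The call of mof was lost without stage 12 embryo B or D (-0.69 and -0.70) and that of mle without stage 12 embryo B, D or H (-0.17 to -0.16). A fall of msl-2 was called without stage 12 embryo C or G (-1.25 and -1.26) or stage 13 embryo D or F (-1.33 and -1.44). Of 17 sex determination genes 12 fell and 0 rose (adjusted p = 0.264 with an estimated correlation), with sisA at -1.07 ± 0.38 and tra at -0.92 ± 0.18. In total 3030 genes were higher and 2445 lower. Non-directional libraries were present at stage 13 and not at stage 12, and among directional libraries 4533 genes were called in both directions together. Adjusted over the list alone, 12 neuron genes rose, and the other counts given were the same. Median, mean and test differed in sign for the glia, trachea and gut lists.

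Between stage 13 (n = 8) and stage 15 (n = 8), every gene of the cell cycle list fell. Most genes of the muscle, neuron and cuticle and epidermis lists rose, but these list calls were lost with an estimated correlation. The muscle myosin gene Mhc rose from 10.1 ± 16.1 to 1697 ± 622 CPM, a log2 change of 7.38 ± 0.45 (adjusted p = 2.62e-19), or 8.52 without stage 13 embryo A. The transmembrane protein genes Osi6 (FBgn0027527), Osi15 and Osi7 rose, Osi6 by 8.77 ± 0.38 to 637 ± 468 CPM, Osi15 by 7.65 ± 0.59 and Osi7 by 7.63 ± 0.35. The X-linked gene sisA fell by 5.93 ± 0.59 (adjusted p = 2.32e-12), with falls for the kinase gene Nek2 at -2.91 ± 0.24, the ecdysone synthesis gene shd at -2.90 ± 0.31 and Inos at -2.79 ± 0.32. All 20 cell cycle genes fell, with a median of -1.37, and the call held with an estimated correlation (adjusted p = 0.0492). Examples were stg at -1.92 ± 0.12, polo at -1.90 ± 0.12 and fzy at -1.88 ± 0.13.

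Of 18 muscle genes 14 rose and 3 fell, with a median of 3.65 (adjusted p = 0.126 with an estimated correlation), including Mp20 at 5.83 ± 0.55, the paramyosin gene Prm at 5.62 ± 0.26 and up at 5.27 ± 0.40. Of 17 neuron genes 12 rose and 2 fell (adjusted p = 0.264 with an estimated correlation). Among those that rose were the synaptic genes Syt1 at 4.47 ± 0.46, nSyb at 3.65 ± 0.29 and brp at 3.53 ± 0.26. Of 12 cuticle and epidermis genes 9 rose and 1 fell (adjusted p = 0.316 with an estimated correlation), with the chitin-binding protein gene Gasp at 5.30 ± 0.36 and sha at 3.89 ± 0.31. Neuroblast genes fell in 13 of 15 cases (adjusted p = 0.201 with an estimated correlation), wor by 1.28 ± 0.20. Gap and pair-rule genes fell in 16 of 18 cases (adjusted p = 0.182 with an estimated correlation), ftz by 2.96 ± 0.43 and hb by 1.31 ± 0.14. Segment polarity genes fell in 6 of 8 cases (adjusted p = 0.264 with an estimated correlation), en by 0.95 ± 0.12. The gut gene mex1 rose by 3.13 ± 0.24, and 5 of 10 hemocyte genes rose and 1 fell. Without stage 13 embryo A the rises were 8.49 for Mp20, 6.125 for up, 6.04 for Gasp and 4.50 for sha.

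In the dosage compensation list roX2 rose by 1.36 ± 0.58 to 121 ± 107 CPM (adjusted p = 0.0419), a call lost with the DESeq2 test, at 1.39, and with library type as a covariate, at 1.20. It was also lost without stage 13 embryo A, B, C, G, H or I or stage 15 embryo A, C, D or I, at 1.14 to 1.23. Single embryos had 11.7 to 145 CPM of roX2 at stage 13, where 2 of 8 were above 100 CPM, and 13.4 to 241 CPM at stage 15, where 4 of 8 were, so the fold also reflects which embryos were sampled. Falls of 0.35 ± 0.10 for msl-1, 0.29 ± 0.09 for Clamp and 0.29 ± 0.07 for mle were not called among directional libraries, with 4 embryos per stage, where the values were -0.27, -0.27 and -0.16. Of 17 sex determination genes 13 fell and 0 rose (adjusted p = 0.114 with an estimated correlation). In total 2818 genes were higher and 2654 lower, and 3633 were called among directional libraries. With p adjusted within the list, 14 sex determination genes fell, 1 gap and pair-rule gene rose, and the other counts given were the same. Median, mean and test differed in sign for the Hox and heat shock lists.

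Between stage 4 (n = 5) and stage 15 (n = 8), the ends of the series, most genes of the neuron, muscle and trachea lists rose and most maternal regulators and cell cycle genes fell, though none of these lists stayed called with an estimated correlation. The extracellular matrix gene Ppn had 1 read at stage 4 and 2487 ± 261 CPM at stage 15. The epidermal gene sha had 0 reads at stage 4 and was at least 12100-fold higher at stage 15, and nur at least 11200-fold. In turn Cyp6a19, a cytochrome P450 gene, had 154 ± 110 CPM at stage 4 and 0 reads at stage 15, at least 2610-fold lower. The log2 change of dhd was -11.65 ± 0.74 (adjusted p = 1.64e-20). Of 21 maternal regulators 18 fell and 1 rose, with a median of -6.72 (adjusted p = 0.0792 with an estimated correlation), among them pgc at -9.83 ± 0.58, bcd at -9.49 ± 0.46, osk at -9.38 ± 0.43 and swa at -8.81 ± 0.43. Of 20 cell cycle genes 17 fell and 0 rose (adjusted p = 0.201 with an estimated correlation), with CycB at -4.89 ± 0.13 and aurA at -4.26 ± 0.20. Cellularization genes fell in 5 of 8 cases and rose in 1.

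All 8 segment polarity genes rose, with a median of 10.18, or 9.82 with absent members at their bound, and the call held with an estimated correlation (adjusted p = 0.037). All 17 neuron genes rose (adjusted p = 0.201 with an estimated correlation), fne and nerfin-1 by at least 7240-fold and 4440-fold. All 18 muscle genes rose (adjusted p = 0.264 with an estimated correlation), TpnC73F by at least 2500-fold. With an estimated correlation the adjusted p of the 9 trachea genes, all of which rose, was 0.0773, and uif rose by 13.27 ± 0.29, or 13.99 without stage 4 embryo H. All 8 Hox genes rose (adjusted p = 0.0773 with an estimated correlation), as did all 7 glia genes (adjusted p = 0.153), all 6 heart genes (adjusted p = 0.126) and all 6 salivary gland genes (adjusted p = 0.264 with an estimated correlation in each case). Neuroblast genes rose in 14 of 15 cases (adjusted p = 0.114 with an estimated correlation), and wor was at least 640-fold higher. Dorsoventral patterning genes rose in 12 of 16 cases and fell in 3 (adjusted p = 0.153 with an estimated correlation), and gap and pair-rule genes rose in 16 of 18 and fell in 2 (adjusted p = 0.126 with an estimated correlation). Cuticle and epidermis genes rose in 10 of 12 cases and fell in 2 (adjusted p = 0.201 with an estimated correlation), serp by at least 9510-fold. Hemocyte genes rose in 9 of 10 cases and fell in 1 (adjusted p = 0.297 with an estimated correlation), PPO2 by at least 2940-fold. Gut genes rose in 6 of 7 cases and fell in 1, GATAe by at least 1890-fold, and the list was not called (adjusted p = 0.101).

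The median of all genes moved by 0.46, by 0.70 with DESeq2 size factors and by 0.71 with the DESeq2 test. Against that shift, 79 of 80 ribosomal protein genes rose, with a median of 1.10 (adjusted p = 0.695 with an estimated correlation). The paralogs RpS5a and RpS5b changed in opposite directions, by 2.27 ± 0.08 and -1.93 ± 0.12. Mitochondrially encoded genes rose in 7 of 15 cases and fell in 1, with a median of 0.50, and heat shock genes rose in 4 and fell in 4 of 8 cases. Dosage compensation genes rose in 4 and fell in 4 of 8 cases. The rises were those of roX1 at 9.40 ± 0.78, msl-2 at 3.63 ± 0.67, mle at 1.14 ± 0.09 and roX2, which went from 1 read to 121 ± 107 CPM. The falls were those of msl-1 at -1.83 ± 0.12, msl-3 at -1.44 ± 0.20, mof at -1.32 ± 0.28 and Clamp at -0.66 ± 0.10. Sex determination genes rose in 8 and fell in 7 of 17 cases. Sxl at 0.87 ± 0.54 was not called (adjusted p = 0.126), and the call of snf at -0.21 ± 0.09 had the opposite sign with DESeq2 size factors. In total 5164 genes were higher and 3489 lower, a share of 59.7% higher, 55.4% relative to the median and 70.8% with the DESeq2 test. Adjusted over the list alone, 4 mitochondrially encoded genes rose, and the other counts given were the same. Median and test differed in sign for the dosage compensation and heat shock lists.

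**Figure D3:**
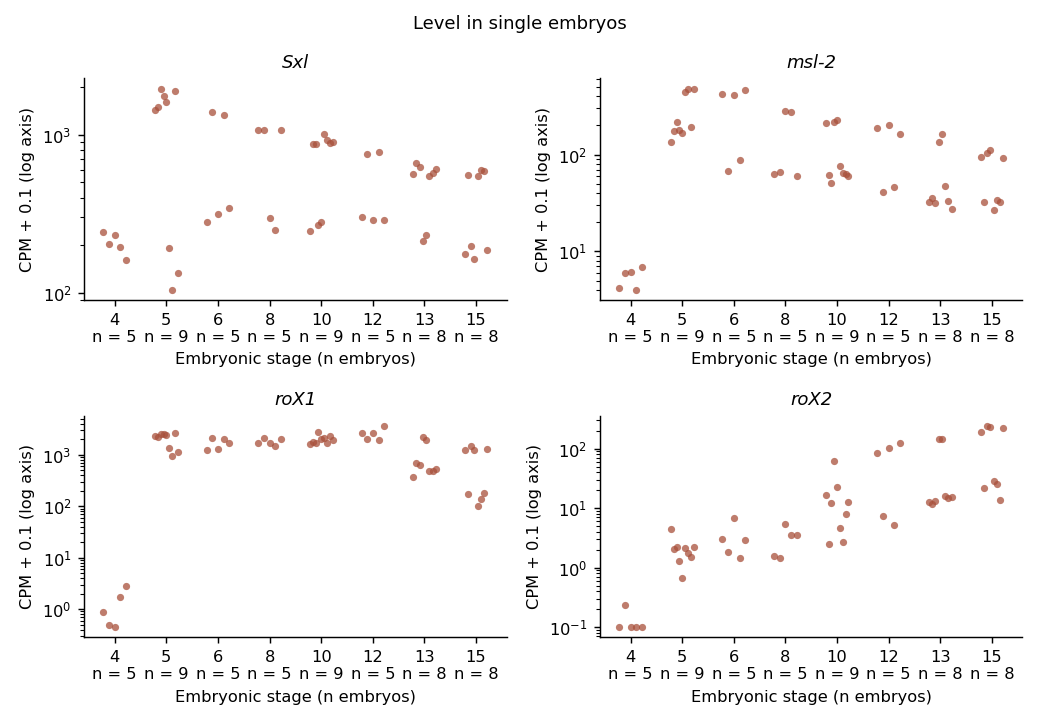
Levels of Sxl, msl-2, roX1 and roX2 in each embryo by stage, in CPM plus 0.1 on a log axis. The SD of Sxl was 32.5 CPM at stage 4 and 792 CPM at stage 5.

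Levels of Sxl, msl-2 and roX1 varied between embryos of a stage. At stage 5 the level of Sxl was 1174 ± 792 CPM (SD, n = 9) and that of msl-2 was 273 ± 147 CPM, against 207 ± 32.5 and 5.33 ± 1.26 CPM at stage 4 (n = 5). At stage 8 (n = 5) msl-2 stood at 150 ± 119 CPM, and at stage 15 (n = 8) at 65.6 ± 37.2 CPM. For roX1 the SD was 379 CPM about a mean of 2017 CPM at stage 10 (n = 9), and 627 CPM about a mean of 730 CPM at stage 15. The labels give no sex, so embryos were not divided by sex and no comparison between the sexes was made.

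The X to autosome ratio was highest at stage 4, with a log2 value of 0.78 ± 0.043 (SD, n = 5). It was 0.19 ± 0.178 at stage 5, -0.0022 ± 0.243 at stage 6, 0.15 ± 0.252 at stage 8, 0.32 ± 0.121 at stage 10, 0.32 ± 0.0958 at stage 12, 0.33 ± 0.0358 at stage 13 and 0.27 ± 0.0582 at stage 15. From stage 4 to stage 5 the ratio fell by 0.59, larger than the spread between embryos (adjusted p = 0.0031, exact permutation test over 2002 arrangements). All 9 embryos of stage 5 lay below all 5 of stage 4. Stage 15 was lower than stage 4 by 0.51 (adjusted p = 0.0031, exact permutation test over 1287 arrangements). Over genes with at least 10 CPM in both stages, a setting chosen after the data were seen, these differences were -0.25 and -0.04 (adjusted p = 0.004 and 0.0435). The differences of -0.19 from stage 5 to 6, 0.15 from stage 6 to 8 and 0.18 from stage 8 to 10 did not pass the exact permutation test (adjusted p = 0.164, 0.36 and 0.164). At stage 6 embryos B, D and H were at -0.208, -0.171 and -0.146 and embryos C and G at 0.33 and 0.183. At stage 8 embryos D and G were at -0.1105 and -0.1347 and embryos B, C and H at 0.236, 0.378 and 0.362. Stage means of the ratio thus also reflect which embryos were sampled. From stage 10 to 12 the difference was -0.01 and from stage 12 to 13 it was 0.02 (adjusted p = 0.934 and 0.753, exact permutation test). From stage 13 to 15 it was -0.06 with an adjusted p of 0.0547 in the exact permutation test, and 0.0205 unadjusted. Without embryo D of stage 13 it was -0.0732 (adjusted p = 0.0278), and without embryo B, G or H of stage 15 it was -0.0749, -0.0703 or -0.0712 (adjusted p = 0.0203, 0.0431 and 0.0394, exact permutation tests). Embryos D and F of stage 13, at 0.268 and 0.313, and embryos A, C, D and I of stage 15, at 0.247, 0.236, 0.204 and 0.19, had the lowest ratios of their stages. The difference between stages 13 and 15 thus also reflects which embryos were sampled. By chromosome, the median log2 change from stage 4 to 5 was 0.34 for the 1607 X genes, 0.83, 0.77, 0.78 and 0.74 for arms 2L, 2R, 3L and 3R, and 1.18 for the 86 genes of chromosome 4.

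**Figure D4:**
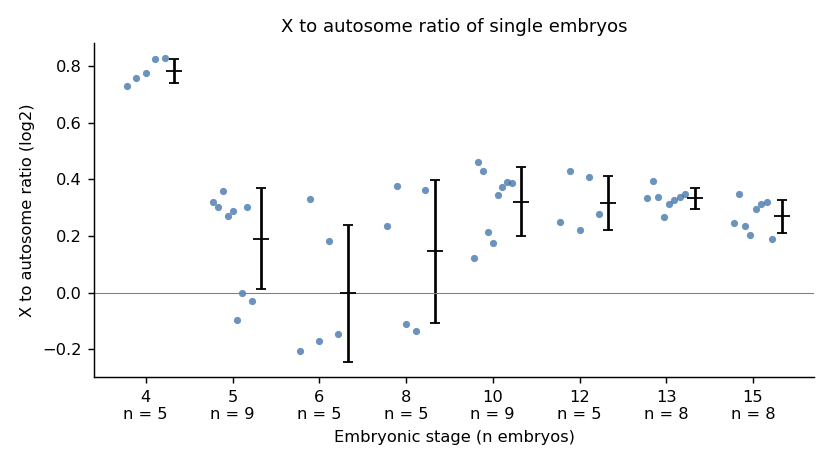
X to autosome ratio of each embryo by stage, as the difference of median log2 CPM, with a point per embryo and the stage mean and SD as bars. The stage 4 embryos lie between 0.732 and 0.83, above the highest embryo of stage 5 at 0.36.

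Within each stage, embryos of the same stage differed in the level of their X genes as a set. The SD of the deviation of the X was 0.0169 at stage 4, 0.0943 at stage 5, 0.181 at stage 6, 0.184 at stage 8, 0.0966 at stage 10, 0.0865 at stage 12, 0.0502 at stage 13 and 0.0464 at stage 15. At each stage it exceeded that of every one of 10000 random sets of autosomal genes matched on expression (adjusted p = 0.0001, the smallest these sets can give). The median SD of the random sets was between 0.002 and 0.0081. The X varied 3.31 to 27.5 times as much as the most variable autosomal arm of the stage. At stage 4 the arms themselves had SDs of 0 to 0.0044. There 12.95% of genes tested were at 0 in every embryo, against 1.91% at stage 5. Such genes have no deviation and draw medians towards 0, so spreads at stage 4 are not fully comparable with those of later stages. Deviations ran from -0.199 to 0.159 at stage 8 and from -0.0466 to 0.0561 at stage 15. Over the 8 stages together, the planned permutation test of the size of deviations from the stage median did not pass (F = 1.55, p = 0.161), which does not show that the spreads were equal. Pairs of stages were compared in tests chosen after the data were seen. In permutation tests of deviations from the stage mean, their mean size was larger at stage 5 than at stage 4, 0.0813 against 0.0137 (adjusted p = 0.012). It was larger at stage 6 than at stage 5 (0.155, adjusted p = 0.018), smaller at stage 10 than at stage 8 (0.0837 against 0.159, adjusted p = 0.018) and larger at stage 15 than at stage 4 (0.0425, adjusted p = 0.0062). Measured from the stage median, only stages 4 and 15 differed (adjusted p = 0.0062), and the other pairs did not pass (adjusted p from 0.564), so those calls rest on the choice of centre.

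**Figure D5:**
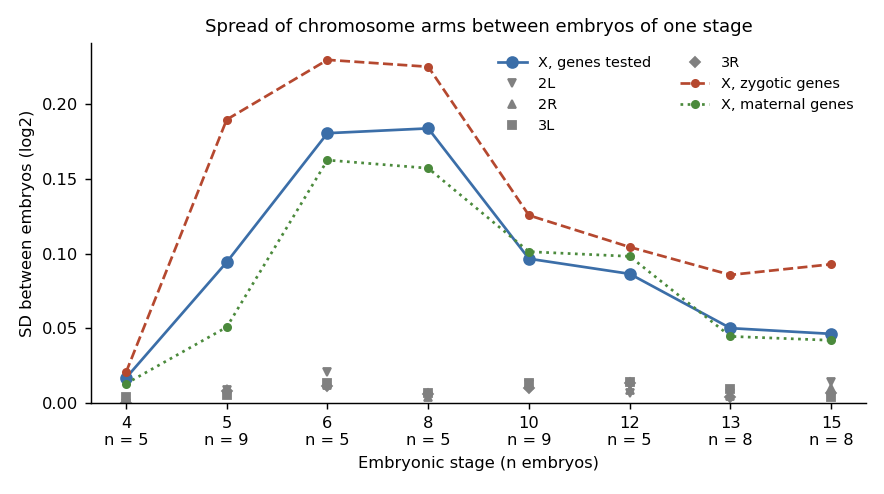
SD between embryos of the deviation of the X, of its zygotic and maternal genes, and of arms 2L, 2R, 3L and 3R, by stage (log2 units). The X lies above every arm at each stage, with its highest value of 0.184 at stage 8.

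Zygotic genes numbered 3587, of which 505 lay on the X and 2997 on the autosome arms, and maternal genes 1940, of which 392 and 1524 did. Over zygotic genes the SD of the X was 0.19 at stage 5, 0.23 at stage 6, 0.225 at stage 8, 0.0858 at stage 13 and 0.0929 at stage 15. Over maternal genes it was 0.0509, 0.163, 0.157, 0.0447 and 0.0421 at these stages. At stages 4, 10 and 12 the values were 0.0206, 0.126 and 0.104 over zygotic genes and 0.0131, 0.101 and 0.0982 over maternal genes. In a test added after the data were seen, with 10000 relabellings of genes, zygotic genes had the larger spread at stages 5, 6, 8, 13 and 15 (adjusted p = 0.0003, 0.0018, 0.0003, 0.0018 and 0.0003). At stages 4, 10 and 12 no difference was detectable (adjusted p = 0.544, 0.143 and 0.719). Genes were relabelled as if independent, which they are not.

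The 200 genes that varied most between embryos of a stage, beyond what their level predicts, held 25 on the X, 12.5% against 16.4% of all genes tested (Fisher's exact test, two-sided p = 0.148). The most variable named gene was mthl8, a relative of the longevity gene methuselah, which ranged from 0 to 82.35 CPM at stage 10. The potassium channel gene slo ranged from 0 to 144 CPM at stage 12, the immunoglobulin superfamily gene DIP-eta from 0 to 60.1 CPM at stage 6, and kek2, which encodes a leucine-rich repeat protein, from 0.81 to 191 CPM at stage 8. The gene ninaC, which encodes a myosin of photoreceptors, ranged from 1.3 to 270.2 CPM at stage 12. The giant muscle protein gene sls ranged from 3.51 to 100.4 CPM at stage 8, and byn from 0.55 to 184 CPM at stage 6. Also among the 15 most variable were jv, AstC-R2, qtc, the ribosomal RNA gene pre-rRNA:CR45845 and the pseudogene 28SrRNA-Psi:CR41609, with 2 genes known by CG numbers and a transporter gene known by its map position. Reads of the pseudogene at stage 15 went with library type, ranging from 142 to 6436 CPM.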

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

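The splits of the embryos were planned, while the wording of what each test would show and all tests of technical and biological explanations in this part were set after the results had been seen.

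Splits of the embryos of 2 stages into groups of the same sizes were refitted, 50 per comparison with the real split included, and 1 of 50, the real split, gave as many changed genes in each comparison. The real counts from these fits of 2 stages and the highest counts of the other splits were 6637 and 2881 for stages 4 and 5, 4382 and 508 for stages 5 and 6, 1733 and 1 for stages 6 and 8, 4215 and 2434 for stages 8 and 10, and 3910 and 0 for stages 10 and 12. They were 5677 and 2800 for stages 12 and 13, 5841 and 0 for stages 13 and 15, and 8191 and 1674 for stages 4 and 15. Over the 8 stages the real count was 9755 and the highest of the other splits, of 30 in all, was 1167. Chance is argued against for these counts of genes, at the resolution of 50 splits per comparison and 30 over the 8 stages. For counts of gene lists called with the preset correlation it is argued against by 1 list only, for stages 5 and 6, with 8 lists against 7 in the highest other split, and for stages 4 and 15, with 18 against 17. These list counts come from the same fits of 2 stages, with lists adjusted within the comparison, and the fit of all 54 embryos called 7 and 16. Chance cannot be excluded for the number of lists called in the other comparisons, but these splits cannot decide the question. A split can hold unequal shares of the 2 stages and so carry part of their difference. Splits with as many lists numbered 22 of 50 for stages 4 and 5 (9 lists, highest other 14), 18 for stages 6 and 8 (4 lists, highest other 7) and 5 for stages 8 and 10 (7 lists, highest other 9). They numbered 10 for stages 10 and 12 (8 lists, highest other 11), 19 for stages 12 and 13 (8 lists, highest other 12) and 23 for stages 13 and 15 (8 lists, highest other 11).

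The X to autosome ratio fell by 0.59 from stage 4 to stage 5, as X genes rose by a median of 0.34 and the autosome arms by 0.74 to 0.83. Genes without reads in 1 of the stages are not the whole cause, since over genes with at least 10 CPM in both stages the difference was still -0.2524, though smaller. Depth does not account for it, since with every embryo thinned to 1630594 reads the difference was -0.5427. A larger loss of maternal RNA from X-linked genes cannot be told apart from other causes, since maternal genes were chosen by their level at stage 4, so that their difference of -0.4675 decides nothing. Zygotic genes had a difference of -0.3619 (unadjusted p = 0.0255, exact permutation test). They were chosen by the same comparison, and so also by their level at stage 4, so this value decides nothing either. The sex of the embryos is not in the labels and was not tested, though all 9 embryos of stage 5, at -0.097 to 0.36, lay below all 5 of stage 4, at 0.732 to 0.83.

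The posterior genes byn and Abd-B were near 0, at 28 reads or fewer, in stage 6 embryo H, stage 13 embryo F and stage 15 embryo C. In stage 6 embryo H the median ratio of other posterior genes to the other embryos was 0.086, with 0 to 0.546 over 4 genes, while head genes stood at 1.457, which is consistent with a missing posterior end. In stage 13 embryo F and stage 15 embryo C the medians of 0.514 and 0.554 lay over low cad (0.215 and 0.208) and otp (0.178 and 0.286) and over HLH54F (0.812 and 0.821) and bowl (1.025 and 1.098) near 1, so a missing posterior end cannot be told apart from other causes. A wrong stage label is argued against, since these embryos and stage 10 embryo J, low in tll and gt, correlated best with their own stage in 4 of 4 cases. Low depth is argued against too, since at the level of the other embryos at least 109.4 reads of byn and Abd-B would have been counted in the 3 embryos low in both, and 68.6 reads of tll or gt in stage 10 embryo J, and no biological explanation was tested.

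Single embryos stood far from the others of their stage in 24 of 312 groups of values tested, where chance flags about 1 in 20 groups, or 15.6. The number is no measure of an excess over chance, since mthl8, DIP-eta, kek2, AstC-R2, sls and byn, which supply 13 of the values, were picked because they vary between embryos. Gene counts were highest in stage 5 embryo B at 5.98 M reads and stage 6 embryo B at 7.96 M reads. Mthl8 stood apart at 0.14 CPM in stage 6 embryo B, 82.35 CPM in stage 10 embryo F, 29.5 CPM in stage 12 embryo B and 18.77 CPM in stage 13 embryo D. DIP-eta had 0.27 CPM in stage 4 embryo C, and kek2 had 98.01 CPM in stage 5 embryo C and 157.83 CPM in stage 6 embryo B. AstC-R2 had 0.07 CPM in stage 4 embryo B and 3.73 CPM in stage 13 embryo D. The muscle gene sls had 23.84 CPM in stage 4 embryo G, 74.23 CPM in stage 6 embryo B and 100.37 CPM in stage 8 embryo G, and byn was lowest in stage 5 embryo G at 38.09 CPM. Among regulators of sex and dosage, msl-1 had 254.63 CPM in stage 8 embryo D, and roX2 had 0.13 CPM in stage 4 embryo C, 4.45 CPM in stage 5 embryo B and 61.11 CPM in stage 10 embryo E. The gene sisA had 58.95 CPM in stage 10 embryo J, sc 5.69 CPM and run 9.18 CPM in stage 4 embryo H, da 296.96 CPM in stage 5 embryo I, and snf was lowest in stage 13 embryo D at 53.9 CPM. In stage 10 embryo J the head genes stood at 0.076 to 1.37 times the other embryos, with a median of 0.631, posterior genes at 0.037 for otp to 2.107 for HLH54F, with a median of 0.951, and byn at 0.083 times. Of trunk genes there, Dfd stood at 0.067, abd-A at 3.016 and Ubx at 2.429 times. Values of 0.07 to 0.27 CPM rest on 1 or 2 reads.

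Reads assigned to no gene, which may include reads of introns, entered no comparison, and what they derive from was not tested. The mean share of such reads among those assigned to a gene, to several genes or to none was 0.328% at stage 4. It was 4.874% at stage 5, 5.083% at stage 6, 4.426% at stage 8, 7.096% at stage 10, 7.49% at stage 12, 5.541% at stage 13 and 4.305% at stage 15. Reads of Y-linked genes, of which a single pseudogene passed the filter and was tested, reached 27.34 per M gene counts, without TMM scaling, in stage 5 embryo G.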

How the results depend on the processing

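Restriction to directional libraries, to genes of at least 10 CPM in the stages compared and to stages 5 to 15 was chosen after the data were seen, as were the tests of library type and number of embryos; the other alternatives were planned. Counts of changed genes stayed within 1.5 times their value in all 8 comparisons with DESeq2, its size factors, no filter, and library type as a covariate. With the title letter as a replicate block, though letters marked no strong pairs, they were 8071, 4737, 1904, 4655, 4815, 5346, 5580 and 8644 in the order of the comparisons. Scaling to spike-in RNAs was not run. Between stages 13 and 15 the count fell from 5472 to 3633 among directional libraries, and to 3608 with their stranded counts. Fewer embryos may account for this, since draws of 4 embryos per stage with both library types gave a median of 3725.5 and a range of 3185 to 4421. Library type itself is argued against, since at most 11 genes differed between the types within a stage and 0 genes differed between them in their change. With an estimated correlation the lists called numbered 2, 2, 0, 0, 0, 0, 1 and 1 in the order of the comparisons, against 9, 7, 5, 6, 7, 6, 8 and 16 with the preset correlation of 0.01, and the estimated correlations were above that preset in all lists.

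The X to autosome ratio kept its direction and its side of the threshold in all comparisons with means over genes, genes with a mean of at least 10 CPM, another prior count, directional libraries and their stranded counts. Over genes with at least 10 CPM in both stages, differences of 0.0995 from stage 12 to 13 and -0.0792 from stage 13 to 15 passed the test (adjusted p = 0.0228 and 0.0162). Over all genes tested, the lowest ratios were those of embryos B, D and H at stage 12, D and F at stage 13 and A, C, D and I at stage 15. Such embryos made up different shares of these stages, so the differences may reflect which embryos were sampled, and the cause was not tested. Leaving out each embryo in turn gave -0.0749 to -0.0525 for stages 13 to 15 (adjusted p = 0.0203 to 0.112), passing without embryo D of stage 13 (-0.0732) and embryos B, G and H of stage 15 (-0.0749, -0.0703 and -0.0712). Embryo D had the lowest ratio of stage 13, at 0.268, and embryos B, G and H the highest of stage 15, at 0.347, 0.315 and 0.321. Each of these omissions thus widened the difference by taking out an extreme embryo. The spread of the X passed at each stage in every alternative run, and its difference over the 8 stages together passed the permutation test in none (p = 0.0653 to 0.277). Leaving out each embryo gave counts of changed genes of 7954 to 8082, 4606 to 4826, 1350 to 1819, 4507 to 5027, 4161 to 4811, 5052 to 5533, 5206 to 5491 and 8537 to 8674. Named-gene values kept direction and side of the threshold in 764 cases with DESeq2 (4 newly passed, 19 no longer passed), 774 with its size factors (2 and 11), 772 with library type (0 and 16), 764 without a filter (0 and 24), 769 with the block (4 and 15), 740 among directional libraries (0 and 40) and 727 with stranded counts (2 and 43). Reversals were da from stage 4 to 5 at 0.163, and dsx at -1.072, 1.588 and 2.333 from stages 5 to 6, 10 to 12 and 12 to 13, all with stranded counts. For dsx, 26.2% of reads without regard to strand lay on its own strand, and for da the cause was not tested. From stage 4 to 15 snf was at 0.036 and 0.042 with DESeq2 size factors and the DESeq2 test, which moved the median of all genes from 0.46 to 0.70 and 0.71. Depth limits genes under about 1 CPM, where 1 embryo holds few reads.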

Other observations

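The tests of the hypotheses in this part, and the genes named in its opening, were chosen after the results were seen.

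Of 6 heart genes 2 rose and 2 fell from stage 10 to 12 and again from stage 12 to 13, and the list was not called in either comparison (adjusted p = 0.94). Hand, a transcription factor gene of heart cells, rose by 4.88 ± 0.46 from stage 10 (n = 9) to stage 12 (n = 5) and by 1.05 ± 0.29 to stage 13 (n = 8), while tin fell by 1.77 ± 0.23 and 1.91 ± 0.24. The T-box gene H15 rose by 3.92 ± 0.45 from stage 12 to 13 and by 1.63 ± 0.24 to stage 15 (n = 8). Of 6 salivary gland genes 4 rose from stage 12 to 13, PH4alphaSG1 by 2.78 ± 0.42 and sage by 1.06 ± 0.33, though that list was not called (adjusted p = 0.469), and from stage 13 to 15 eyg fell by 0.85 ± 0.34. That call was lost when adjusted over the list alone, and without stage 13 embryo D (-0.78) or stage 15 embryo F (-0.80). The tracheal fusion cell gene dysf rose by 4.31 ± 0.51 from stage 10 to 12 and by 2.4 ± 0.33 to stage 13. The maternal regulator dl, low since stage 5, rose by 3.49 ± 0.45 from stage 12 to 13 and by 2.90 ± 0.23 to 47.0 ± 11 CPM at stage 15. Leaving out 1 embryo moved the rise of Hand to 5.50 (stage 10 embryo G), that of dysf to stage 12 to 4.92 (stage 10 embryo E) and that of PH4alphaSG1 to 3.41 (stage 12 embryo G).

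Genes of chromosome 4, a small and largely heterochromatic autosome, had a higher median change than all genes from stage 4 to stages 5 and 15, though not in every comparison. Of its 86 genes tested 66 were higher and 10 lower at stage 5 than at stage 4, with a median log2 change of 1.18 against 0.72 for all genes. At stage 15, 65 were higher and 13 lower than at stage 4, with a median of 1.49 against 0.46. From stage 12 to 13, 19 were higher and 32 lower, with a median of -0.19 against 0.04. The difference between chromosome 4 and the other chromosomes was not tested. Among X genes 64.5% had at least 10 CPM at stage 4, 58.3% at stage 5 and 71.1% at stage 15, against 57.6, 56.2 and 67.6% of autosomal genes.

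Levels of Sxl and msl-2 fell into separate clusters of embryos within stages. At stage 5 Sxl was at 190, 104 and 133 CPM and msl-2 at 439, 478 and 481 CPM in embryos G, H and J, with deviations of the X of -0.154, -0.0975 and -0.1 and 116, 81 and 99 Y-linked reads. In embryos B, C, D, E, F and I Sxl was at 1443, 1491, 1963, 1759, 1603 and 1880 CPM and msl-2 at 134, 177, 215, 178, 166 and 191 CPM, with 4, 3, 1, 5, 1 and 1 Y-linked reads. At stage 6 Sxl was at 282, 315 and 344 CPM in embryos B, D and H and at 1395 and 1333 CPM in embryos C and G, with 106, 60 and 65 Y-linked reads against 4 and 1. At stage 8 it was at 295 and 250 CPM in embryos D and G and at 1074, 1064 and 1065 CPM in embryos B, C and H. At stage 15 roX1 was at 1230, 1490, 1219 and 1306 CPM in embryos A, C, D and I and at 175, 103, 139 and 179 CPM in embryos B, F, G and H, and roX2 at 190, 241, 231 and 221 CPM against 21.9, 29, 25.1 and 13.4 CPM. At stage 13 embryos D and F had 2188 and 1970 CPM of roX1 and 145 CPM of roX2 each, and at stage 12 embryos B, D and H had 2651, 2710 and 3662 CPM of roX1 and embryos C and G 2035 and 1954 CPM. These clusters held different shares of the embryos of a stage, so stage means of these genes and of the X to autosome ratio depend on which embryos were sampled. At stage 4 no clusters stood out, with 17 to 46 Y-linked reads in every embryo and deviations of the X from -0.0274 to 0.0135. These clusters were read from the measured values, so they were neither averaged nor tested, and sex was not assigned.

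A hypothesis was that the spread of the X between embryos of stage 5 arises in newly transcribed genes. The SD over zygotic genes exceeded that over maternal genes by 0.1387 (adjusted p = 0.0003, 10000 relabellings of genes), as the hypothesis predicts. The result had been seen before the hypothesis was tested, so it is no independent support. Genes were also relabelled as if independent, which they are not.

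A further hypothesis was that genes present in some embryos and near 0 in others reflect variants linked on a chromosome. Among 165 variable autosomal genes, 529 pairs lying 50 kb to 2 Mb apart had a median absolute correlation of 0.146, against 0.115 for 6786 pairs on different chromosomes. For near pairs against all other pairs of these genes, the one-sided p over 10000 shuffles of position was 0.0001, the smallest these shuffles can give. The difference in medians is small, and 3.4% of near pairs against 1.74% of pairs on different chromosomes reached an absolute correlation of 0.6. It also rests in part on stage 10 embryo J, without which the medians were 0.128 and 0.115. Near pairs against all other pairs then gave a one-sided permutation p of 0.0276 over 10000 shuffles, a check added after the data were seen. The strongest near pair, erm and Gsc at 1371.2 kb (r = 0.923), were both at 0 CPM in that embryo, and without it their correlation was 0.85. Genes that share regulation may also lie close together, so this is a candidate explanation only.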
